A study of Mus musculus with 24 samples.

How the data were processed

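Gene expression was measured on Affymetrix microarrays in the distal femur of C57BL/6J mice. Purified mouse skeletal stem cells (mSSCs) and whole bone tissue (bulk) were profiled from newborns at postnatal day 3 and from adults of 9 to 25 weeks, with uninjured or microfractured joints. Per the labels' protocols, 500 to 1000 stem cells were sorted straight into TRIzol LS, bulk bone was frozen and crushed, and RNA was amplified through 2 rounds with a RiboAmp PLUS kit before labelling. The sort kept cells negative for CD45, TER119, TIE2, THY1, 6C3 and CD105 and positive for integrin alpha V. RNA from so few cells reaches an array only after strong amplification, so low values carry more error than high ones, and RNA of a small number of other cells can be amplified with that of the target cells.

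The deposited values came in 2 tables with different units. For the 10 replicated sorted-cell arrays the authors deposited linear MAS5 intensity per gene, with probes regrouped into 18052 genes by a custom probe definition. MAS5 is named in the submitters' processing notes, and its version, the annotation and the scaling target are not given in the sources used here. The 2% trimmed mean of this intensity lay between 490.3 and 495 on all 10 arrays, so the arrays had been brought to a shared mean. For the 11 bulk arrays and the 3 arrays of factor-treated joints the authors deposited a gene expression activity score for 45101 probe sets, bounded at -100 and 100. How the score was computed, and what 0 stands for, are not given in the sources used here. A score near either bound can move little further, so differences were given in score points and never as folds. The smaller per-platform value tables held the same numbers (0 of 180520 and 0 of 631414 values differed) and were not analysed apart.

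Arrays were grouped by their titles. Sorted cells comprised 4 newborn, 3 uninjured adult and 3 microfractured adult arrays. Bulk tissue comprised 3 newborn, 5 uninjured adult and 3 microfractured adult arrays. The 3 arrays of sorted cells from microfractured joints given PBS, BMP2 or VEGFR1 stood alone, with 1 array per treatment. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

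For the sorted cells, 17994 of 18052 rows were matched by Entrez gene ID to the reference gene table (assembly GRCm38.p6), which was used only for current symbols. For the score table, 38557 probe sets carried 1 symbol, 860 carried several and 5684 carried none. Only probe sets with 1 symbol were used, and a gene was represented by its probe set with the highest mean. Intensity was tested as log2(value + 16), so a fold is on that scale and understates the change of low genes. Scores were tested as deposited. A gene was kept when its value exceeded the median of all values in the table (250.4 intensity units, or a score of -16.4) in at least 3 arrays, which left 10893 genes in sorted cells and 16587 in bulk tissue. A gene high in a single group could pass, which favours calls in that direction among the genes kept.

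The 3 groups of each kind were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend, 2-sided, group as the only term). Benjamini-Hochberg adjustment was applied over all genes tested, with a threshold of 0.05. The errors given with differences are limma's standard errors, and those given with means are standard deviations. Standard errors pool the spread of all 3 groups. Errors and p-values between the 2 adult sorted groups thus rest partly on newborn arrays, whose replicates correlated most closely. Groups of genes were tested with camera at a preset correlation of 0.01 on 27 lists, again with a correlation estimated per list, and with fry. Camera compares a list with all other genes. Fry's p tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined.

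The rule named the 10 genes with the largest rise and the 10 with the largest fall among non-overlapping calls with official symbols, the 4 members of each list with the smallest p, and always the genes of the sort together with Bmp2, Flt1, Kdr, Vegfa, Sox9, Acan, Col2a1, Col1a1 and Runx2. Where no gene passed, it named the 5 higher and 5 lower genes with the smallest unadjusted p. For the factor arrays it named the 10 highest and 10 lowest differences and the genes always named. Some genes under the rule were left out for length, and a few are not reported here, and genes outside it are said to be so.

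The fixed plan had expected values on a scale that allows folds for the factor arrays. Because scores do not, a difference of at least 50 score points replaced a 2-fold change there, a choice made once the unit was known, and genes were compared when the higher of the 2 scores exceeded the 75th percentile of the table (42.8). With 1 array per treatment no test was made. The median difference of each list was ranked among 10000 random lists of the same size matched on mean score. Sorted cells and bulk tissue could not be set against each other in a test, since no table held replicates of both.

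The test was tried on simulated data in which 67, 67 and 66 genes per draw were given known changes of 3 sizes, over 10 draws. In the simulation of microfractured against uninjured adult sorted cells over 10893 genes, 33.9% of genes changed by 1 on the log2 scale, 84.9% of those changed by 2 and 95.8% of those changed by 3 were called. For newborn against uninjured adult sorted cells these shares were 42.7%, 87.8% and 95.6%, and for newborn against microfractured adult 41.6%, 87.0% and 96.5%. In the simulation of microfractured against uninjured adult bulk tissue over 16587 genes, 1.04% of genes moved by 30 points, 2.99% of those moved by 60 and 6.82% of those moved by 90 were called. For newborn against uninjured adult bulk tissue these shares were 0.299%, 1.49% and 8.94%, and for newborn against microfractured adult 0.896%, 1.64% and 4.09%. In the simulation few bulk genes were thus called even at 90 points, so a missing bulk call does not show that a gene was unchanged. The adjusted threshold is stricter when fewer genes change. In the data limma called 1087, 259 and 0 bulk genes (newborn against uninjured, newborn against microfractured, and microfractured against uninjured adult). The shares may therefore understate recovery where many genes differ. Scores are bounded, so simulated changes near a bound may have been smaller than stated. The simulation thus does not settle which bulk genes could be called in the data.

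Alternatives changed the scaling between arrays, the filter, the pseudocount, the variance model, array weights, the representation of a gene, the arrays in the fit, a block for the replicate number, the list test and each array in turn. Counts without genes rich in marrow, without X and Y genes, with a logit of the score and without the 2 bulk arrays that correlated least with their groups were added after the data were seen.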

Results

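The series measured gene expression on 24 arrays from the mouse distal femur, the part of the thigh bone that forms the knee. Skeletal stem cells, which give rise to bone, cartilage and stroma, were sorted from newborns (4 arrays), uninjured adults (3 arrays) and adults with microfractured joints (3 arrays). Microfracture is a surgical treatment that perforates the bone beneath joint cartilage so that cells from below can fill a defect. Bulk bone tissue was measured in 3 newborn, 5 uninjured adult and 3 microfractured adult arrays, and 3 single arrays held stem cells from microfractured joints given PBS, BMP2 or VEGFR1. Sorted-cell replicates correlated at 0.951 to 0.967 across genes in newborns, 0.887 to 0.934 after microfracture and 0.832 to 0.902 in uninjured adults. Bulk replicates correlated at only 0.417 to 0.616 in newborns, 0.560 to 0.788 in uninjured adults and 0.577 to 0.635 after microfracture. The array number limits the precision throughout.

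The first comparison asked what microfracture changed in adult stem cells. Sox9, the regulator that starts the cartilage programme, rose from 802 ± 164 to 1979.6 ± 881 intensity units (SD, n = 3 and 3; log2 difference 1.22 ± 0.27, adjusted p = 0.00654, limma), and its partner Sox5 rose by 1.34 ± 0.19. Col10a1, the collagen of hypertrophic cartilage, rose from 1331 ± 616 to 6404 ± 2058 (2.30 ± 0.32, adjusted p = 0.00104). The cartilage matrix genes Acan (8318 ± 249 after microfracture, 6601 ± 1047 without; adjusted p = 0.173) and Col2a1 (12251 ± 1754 and 14916 ± 3746; adjusted p = 0.416) did not pass. Cytl1, a secreted cartilage factor, fell by 1.07 ± 0.21, and Matn1, a matrix protein of immature cartilage, fell by 1.97 ± 0.35. Of 22 cartilage genes tested, 2 rose, 3 fell and 17 did not pass, and camera did not set the list apart (adjusted p = 0.794).

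Genes of energy use were higher after microfracture. Of 9 glycolysis genes 6 rose, among them Tpi1 (1.67 ± 0.22), Aldoa (1.14 ± 0.16) and the glucose transporter Slc2a1 (1.34 ± 0.25), and the list median lay 0.86 above that of all genes (camera adjusted p = 0.000829; adjusted p = 0.176 with an estimated correlation). Of 13 oxidative phosphorylation genes 4 rose, with a relative median of 0.51 (0.016; 0.176 with an estimated correlation). Genes with high signal tended to be higher after microfracture as a class. With a filter at the 75th percentile the median difference of all 5679 genes was 0.24, against -0.04 in the main run. Part of these relative medians may come from that. Single matrix genes also rose. Timp1, an inhibitor of matrix breakdown, rose by 1.25 ± 0.17, and the collagen gene Col5a1 rose by 1.28 ± 0.22. The signal Tgfb1 rose by 1.67 ± 0.37 and the matrix protein Tgfbi rose by 1.29 ± 0.21. Of 21 fibrous matrix genes 6 rose and 1 fell, which did not pass as a list (adjusted p = 0.0631). The growth factor Bmp2 rose from 3410.2 ± 607 to 4952 ± 801 (adjusted p = 0.0460) and Vegfa, which draws in vessels, from 1497 ± 313 to 2744 ± 1188 (adjusted p = 0.0483). Both calls ended with quantile normalization, as did those of Matn1, Mcm2 and Cdkn1a.

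Cell cycle genes were lower after microfracture. Of 21 cell cycle genes 10 fell and 0 rose (11 fell when adjusted over the list alone), with a relative median of -0.73 (camera adjusted p = 0.00159; adjusted p = 0.33 with an estimated correlation). Rrm2, which makes DNA building blocks, fell by 1.34 ± 0.29, and the replication helicase gene Mcm2 fell by 0.96 ± 0.23, while the cell cycle inhibitor Cdkn1a rose by 0.72 ± 0.18. Cdkn1a went against its list: the 10 inhibitor and senescence genes had a relative median of -0.35. With arrays centred on their medians the calls of Rrm2, Mcm2 and Cytl1 ended. Rrm2 was also lower in newborn than in uninjured adult bulk tissue (-58.2 points, adjusted p = 0.0489, limma), as were Top2a and Ccna2. They are thus among the genes taken below as rich in marrow. Whether RNA of marrow cells in the uninjured arrays contributed to the fall of cell cycle genes was not tested. The BMP antagonist Grem1 fell by 2.07 ± 0.22 and the leptin receptor Lepr by 1.69 ± 0.31, and of 14 stem and stromal genes 7 fell and 1 rose, which did not pass as a list (adjusted p = 0.264).

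Blood cell markers moved with these groups. Ptprc, which encodes the CD45 protein that the sort selects against, was 3462 ± 367 in uninjured adult, 651 ± 132 in microfractured adult and 58.7 ± 21.1 in newborn stem cells. The myeloid gene Lyz2 read 16418 ± 2191, 4996 ± 3167 and 668 ± 82.3. Slc4a1, an anion exchanger gene, fell from 1804 ± 436 in uninjured to 408 ± 268 in microfractured adult stem cells. After microfracture 14 of 15 myeloid, 10 of 10 erythroid, 4 of 6 lymphocyte and 4 of 4 endothelial genes fell. Their relative medians were -1.69, -2.21, -2.53 and -2.01 (camera adjusted p = 2.9e-06, 6.1e-06, 0.0051 and 0.024), and with an estimated correlation adjusted p was 0.24, 0.176, 0.176 and 0.24. A gene could pass the filter through the 3 uninjured adult arrays alone, so the filter partly favoured such falls. The tested lymphocyte and endothelial genes averaged 9.12 and 8.66 there on the log2 scale, against 6.68 and 6.56 after microfracture. Dntt, an enzyme of immature lymphocytes, fell by 4.23 ± 0.54, and the endothelial receptor gene Tek fell by 2.07 ± 0.45. The chemokine gene Ccl3 fell by 2.08 ± 0.32 while the neutrophil attractant Cxcl1 rose by 2.10 ± 0.37. Some of the largest falls were in genes usually found in other tissues, such as H2-M10.1 (-4.72 ± 0.65), Prl3d1 (-4.44 ± 0.81) and Igfbp1 (-4.34 ± 0.64). No list of such genes was fixed or tested.

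In all, limma called 3606 of 10893 genes between microfractured and uninjured adult stem cells, 1453 higher (40.3%) and 2153 lower, and 2247 of them differed at least 2-fold. Groups did not overlap for 41.1% of genes, where chance gives 10%. The direction split depended on the scale between arrays, the filter and the uninjured adult arrays. Median-centring, which moved the median of all genes by 0.65, called 4882 higher and 929 lower, and quantile normalization, which moved it by 0.14, called 1492 higher and 1315 lower. The count was 1806 without uninjured adult replicate 1 (54.0% of them higher), 1880 without replicate 2 (55.6%), 1914 without replicate 3 (55.4%) and 2226 without microfractured replicate 3. It was 6242 without a filter (1549 higher and 4693 lower), 1742 with a filter at the 75th percentile (1233 and 509) and 2262 with the 2 groups fitted alone. Leaving out an uninjured adult replicate also left fewer genes to test (9824, 9859 and 9858 in turn). Genes above the filter in uninjured adults alone could no longer pass it, so the split partly reflects the filter. The median and mean differed in sign for the imprinted growth and osteoclast lists, and fry set the Wnt list lower although its median was higher, and none of these passed camera. The largest rise by the naming rule included Slc39a1, a zinc transporter gene (4.17 ± 0.33, adjusted p = 8.22e-05).

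**Figure D1:**
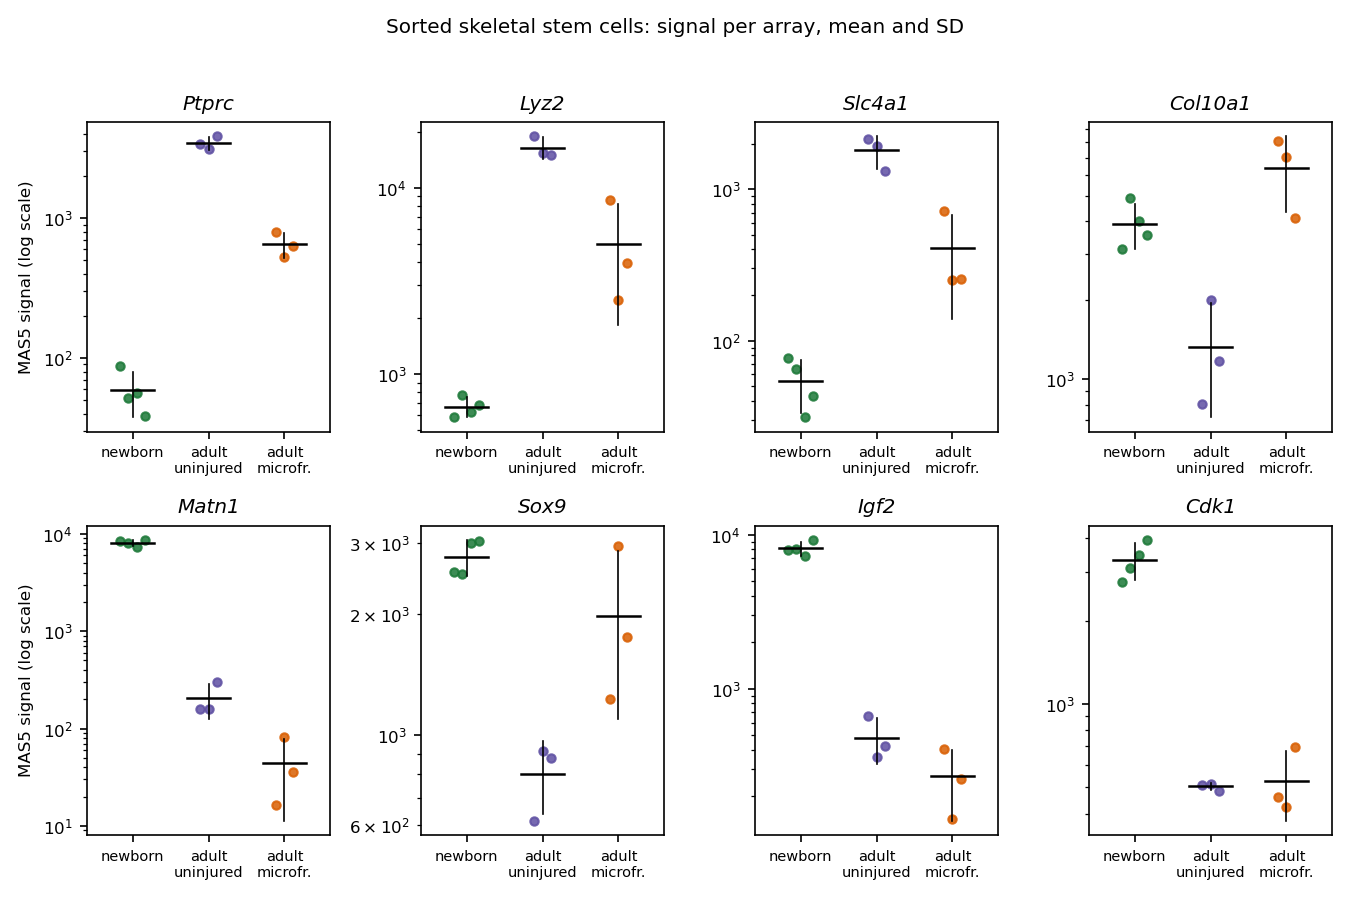
Expression of named genes in sorted stem cells, as MAS5 intensity on a log axis, with points for single arrays, horizontal lines for means and vertical lines for the SD in newborn (4), uninjured adult (3) and microfractured adult (3) groups. Ptprc averaged 58.7, 3462 and 651 in these groups, and Sox9 averaged 2777, 802 and 1979.6.

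The second comparison asked how newborn stem cells differ from uninjured adult ones. The fetal growth genes Igf2, a growth factor (8133 ± 834 against 481 ± 158, SD, n = 4 and 3; log2 difference 4.08 ± 0.29), Mest (4.38 ± 0.18) and Igf2bp2, which binds growth factor RNA (3.57 ± 0.28), were higher in newborns, and all 14 genes of the imprinted growth network rose. This list kept its call with an estimated correlation (camera adjusted p = 7.03e-10, and 0.00509 with an estimated correlation; relative median 2.64). Cartilage genes were also higher in newborns: 16 of 22 rose and 4 fell (17 and 4 when adjusted over the list alone). Matn1 rose by 5.25 ± 0.32, Epyc, a cartilage proteoglycan gene, by 4.16 ± 0.49 and Sox9 by 1.79 ± 0.26. Acan rose by 0.83 ± 0.18, whereas Col2a1 fell by 1.36 ± 0.22 and Prg4, which encodes the joint lubricant, fell by 3.62 ± 0.25. The cartilage list passed camera (0.00173; adjusted p = 0.217 with an estimated correlation).

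Bone and stromal genes were lower in newborns. Of 15 osteoblast genes 14 fell and 1 rose, with Ibsp, a mineral-binding matrix gene, falling by 4.57 ± 0.25 and Alpl, a mineralization enzyme gene, by 2.43 ± 0.23 (camera adjusted p = 8.38e-06; 0.125 with an estimated correlation). The collagenase gene Mmp13 fell by 5.68 ± 0.24. Of 14 stem and stromal genes 10 fell, among them Cxcl12 (-3.74 ± 0.23), which with Kitl (-3.12 ± 0.24) holds blood stem cells in marrow, and Lepr (-2.85 ± 0.29), a marker of the stromal cells around them (0.000944; 0.151 with an estimated correlation). Of 21 fibrous matrix genes 13 fell and 3 rose (0.0112; 0.334 with an estimated correlation), with the protease gene Fap falling by 3.75 ± 0.20. Of 21 cell cycle genes 13 rose and 0 fell, with the division kinase Cdk1 rising by 2.68 ± 0.20 and the cyclin Ccnb1 by 2.46 ± 0.28 (6.14e-05; 0.185 with an estimated correlation). Of 18 BMP pathway genes 8 rose and 1 fell, with the BMP target Id1 rising by 2.06 ± 0.28 (0.00764; 0.294 with an estimated correlation).

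Blood markers were lower in newborn than in uninjured adult stem cells. All 15 myeloid, 10 erythroid and 5 osteoclast genes fell, and so did 5 of 6 lymphocyte, 9 of 14 inflammatory and 4 of 6 adipocyte genes. Here too a gene could pass the filter through the 3 uninjured adult arrays alone. The low end of the signal was also higher in those arrays. The median of olfactory and vomeronasal receptor genes averaged 155 intensity units there and 22.0 in newborns. Whether this contributed to the falls of genes with low signal in newborns was not tested. Ptprc fell by 5.58 ± 0.24, Il1b, an inflammatory cytokine gene, by 6.53 ± 0.43, Car2 by 6.23 ± 0.37 and Mmp9 by 5.14 ± 0.43. Camera gave adjusted p = 2.47e-09 (myeloid), 2.49e-07 (erythroid), 0.0139 (osteoclast), 0.00421 (lymphocyte), 0.00412 (inflammatory) and 0.0421 (adipocyte), and with an estimated correlation 0.125 for the first 4, 0.191 and 0.247. The Wnt inhibitor genes Sfrp1 and Sfrp4 moved apart (3.41 ± 0.22 and -6.10 ± 0.29), as did the hedgehog genes Gli3 (1.60 ± 0.18) and Hhip (-2.70 ± 0.21). limma called 5945 genes between newborn and uninjured adult stem cells, 2743 higher and 3202 lower, of which 3867 differed at least 2-fold, and groups did not overlap for 61.0% of genes (chance 5.71%). Median-centring moved the median of all genes by 0.70 and called 5702 higher and 1789 lower, and quantile normalization called 3028 and 2548. The count was 9549 without a filter (2840 higher and 6709 lower) and 3369 with a filter at the 75th percentile (2272 and 1097). Of the calls 46.1% were higher, against 53.9% without uninjured adult replicate 1, 55.4% without replicate 2 and 54.9% without replicate 3. Those runs tested only 9824, 9859 and 9858 genes, as genes above the filter in uninjured adults alone dropped out.

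The third comparison set newborn against microfractured adult stem cells. All 21 cell cycle genes and all 14 imprinted growth genes were higher in newborns (camera adjusted p = 2.65e-11 for both). With an estimated correlation adjusted p was 0.0881 for the cell cycle and 0.00351 for imprinted growth. The kinase genes Cdk1 and Aurkb rose by 2.64 ± 0.20 and 2.37 ± 0.22, Igf2 by 4.94 ± 0.29 and the stem cell regulator Dlk1 by 5.15 ± 0.31. Of 22 cartilage genes 13 rose and 4 fell (16 and 4 when adjusted over the list alone; camera adjusted p = 0.00126, and 0.166 with an estimated correlation). Matn1 rose by 7.22 ± 0.32, while Sox9 read 2777 ± 285 in newborns and 1979.6 ± 881 after microfracture and did not pass (adjusted p = 0.0993). The BMP antagonist Grem1 rose by 2.46 ± 0.20, and Bmp2 itself did not pass (5109 ± 441 and 4952 ± 801; adjusted p = 0.846).

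Bone, wound and VEGF pathway genes were lower in newborns than after microfracture. Of 15 osteoblast genes 10 fell, with Ibsp falling by 4.45 ± 0.25 (camera adjusted p = 6.17e-06; 0.0881 with an estimated correlation), and of 21 fibrous matrix genes 12 fell and 1 rose (2.56e-06; 0.166 with an estimated correlation), with S100a4 falling by 4.74 ± 0.28 and the collagen cross-linker Lox by 3.32 ± 0.27. Of 7 VEGF pathway genes 6 fell, with camera adjusted p = 0.00723 (0.155 with an estimated correlation). Vegfa fell by 0.74 ± 0.27 (adjusted p = 0.0486), a call that ended with quantile normalization, median-centring, no filter, no variance trend, a replicate block, the 2 groups fitted alone and 5 of the arrays left out in turn. Tgfb1 fell by 3.41 ± 0.34, the inhibitor Cdkn1a by 1.28 ± 0.16, and the proteases Mmp3 and Mmp13 by 6.47 ± 0.52 and 4.87 ± 0.24. The 10 inhibitor and senescence genes had a relative median of 0.21, opposite to Cdkn1a. Myeloid and erythroid markers were again lower, 10 of 15 and 10 of 10 genes, with Ptprc falling by 3.18 ± 0.24 (1.62e-06 and 2.02e-05; 0.166 and 0.155 with an estimated correlation). limma called 3997 genes between newborn and microfractured adult stem cells, 2006 higher and 1991 lower, of which 2462 differed at least 2-fold, and groups did not overlap for 42.8% (chance 5.71%). A filter at the 75th percentile gave 2628. The Wnt list, which did not pass, had a higher median and a lower mean, and in newborns against uninjured adults the cell cycle inhibitor list had a lower median and a higher mean.

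**Figure D2:**
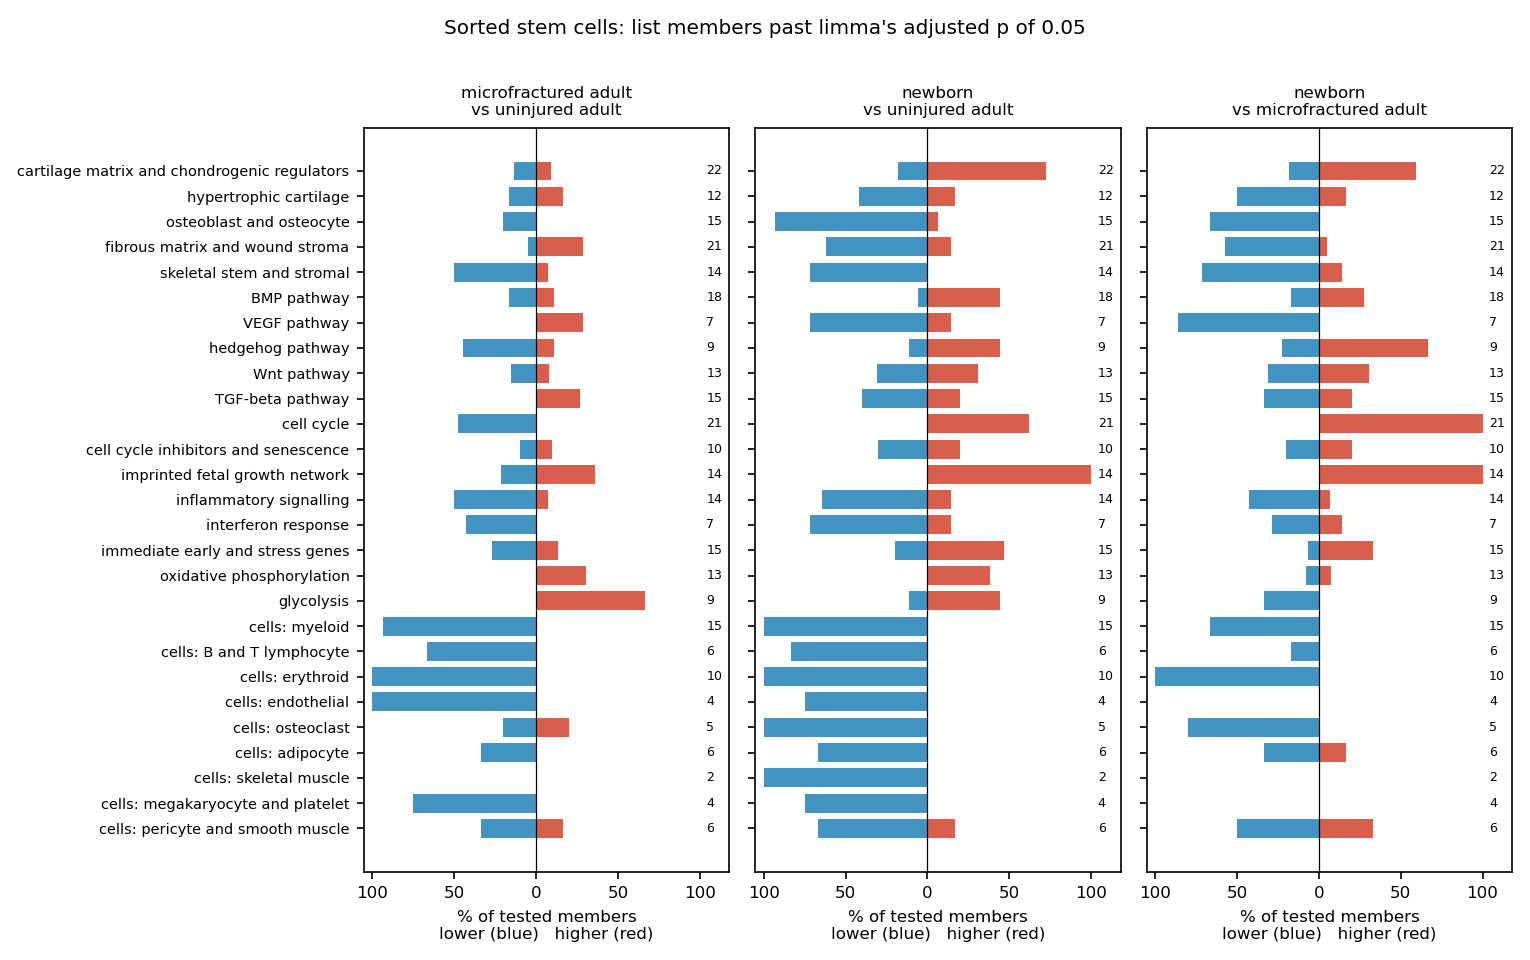
Bars give the percentage of each list's tested genes called higher (right) or lower (left) by limma in the 3 comparisons of sorted stem cells, with the number tested at the right. Of 21 cell cycle genes, 10 were lower after microfracture, 13 were higher in newborns than in uninjured adults and 21 were higher in newborns than after microfracture.

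Both the newborn and the microfractured groups were set against the same uninjured adult arrays, so their differences share error. Across 10893 genes these differences correlated at 0.592, where simulated unchanged groups against shared controls gave 0.533 (0.509 to 0.564). The simulation gave every group the same spread, whereas uninjured adult replicates correlated least with each other (0.832 to 0.902). A wider spread in the shared arrays would raise the simulated value, so 0.592 shows no clear excess. The covariance was 0.733 against 0.0639 simulated. Of the genes called, 863 were higher in both and 1497 lower in both, where independent lists would share 366 and 633, and 164 and 127 moved in opposite directions against 427 and 542. The numbers for independent lists do not allow for the shared arrays. No split of 3 control arrays leaves 2 in each part and none was run, so part of the excess may come from the shared arrays. In bulk tissue r was 0.445 (0.375 simulated) with a covariance of 727 (347 simulated), and with the 5 controls split between the comparisons r was 0.219 (0.147 to 0.243 over splits) with a covariance of 426.

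In bulk tissue, fetal growth and cartilage genes were higher in newborns than in uninjured adults. Igf2 rose by 135.14 ± 16.49 score points (98.2 ± 1.93 against -36.9 ± 24.1, SD, n = 3 and 5; adjusted p = 0.00181), Meg3, an imprinted RNA gene, by 103.34 ± 15.36 and the growth inhibitor Cdkn1c by 98.00 ± 15.88. Of 16 imprinted growth genes 8 rose (11 when adjusted over the list alone; camera adjusted p = 3.22e-09, and 0.00323 with an estimated correlation). Of 21 cartilage genes 5 rose (12 when adjusted over the list alone; 1.79e-08, and 0.00323 with an estimated correlation), among them Matn1 (62.36 ± 13.67), Chad (95.25 ± 23.07) and Ucma (72.26 ± 18.37). Sox9 was 86.6 ± 12.1 in newborns and -42.3 ± 34.6 in adults and did not pass (adjusted p = 0.0571). The hedgehog effectors Gli3 (115.28 ± 14.69) and Gli2 (84.30 ± 18.45) and the Wnt inhibitors Sfrp1 (133.25 ± 20.52) and Frzb (97.19 ± 19.47) rose, and 4 of 13 hedgehog and 5 of 16 Wnt genes passed upward (0.000686 and 0.000414; 0.0204 and 0.0293 with an estimated correlation).

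Marrow and immune genes were lower in newborn bulk tissue. Of 16 myeloid genes 11 fell and of 13 erythroid genes 10 fell (15 and 12 when adjusted over the list alone), such as Ptprc (-137.52 ± 19.36) and the red cell membrane gene Epb42 (-84.17 ± 11.82) (camera adjusted p = 1.46e-11 and 1.84e-09; 0.00452 and 0.0149 with an estimated correlation). Of 10 interferon response genes 4 fell, such as the antiviral gene Rsad2 (-108.95 ± 15.48), and of 5 platelet genes 3 fell (4.17e-06 and 0.000414; 0.02 and 0.02 with an estimated correlation). Of 24 cell cycle genes 5 fell and 0 rose, such as Top2a (-68.99 ± 15.44) and Ccna2 (-42.82 ± 9.06) (1.61e-07; 0.0764 with an estimated correlation). The osteocyte genes Phex (-97.95 ± 10.39) and Mepe (-86.61 ± 18.53) fell, while the osteoblast list did not pass (adjusted p = 0.102). limma called 1087 of 16587 genes between newborn and uninjured adult bulk tissue, 344 higher and 743 lower, of which 1026 differed by at least 50 points, and groups did not overlap for 16.5% (chance 3.57%). The count was 664 without uninjured adult replicate 2, 609 without replicate 3, 653 without replicate 4 and 637 without newborn replicate 3. It was 719 with a filter at the 75th percentile (155 higher and 564 lower) and 0 with a block for the replicate number. The split was 259 higher and 805 lower without newborn replicate 1, 227 and 580 without replicate 2 and 144 and 493 without replicate 3. The median and a test differed in sign for the stem and stromal and the cell cycle inhibitor lists here and against microfractured adults, and neither passed camera.

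Against microfractured adult bulk tissue, newborns again had higher Igf2 (98.68 ± 18.43), Cdkn1c (105.76 ± 17.76), Gli2 (117.51 ± 20.63) and Pgk1, a glycolysis gene (94.74 ± 19.52), and lower Ptprc (-139.82 ± 21.65), Phex (-94.02 ± 11.61) and Dcstamp, which fuses osteoclasts (-141.62 ± 26.72). Of 21 cartilage genes 0 passed over all genes and 10 rose when adjusted over the list alone, and the list passed camera (adjusted p = 1.64e-09; 0.00267 with an estimated correlation). Of 16 imprinted growth genes 3 rose (9 when adjusted over the list alone; 8.33e-07, and 0.00939 with an estimated correlation), and of 10 osteoclast genes 3 fell (9.19e-05; 0.0466 with an estimated correlation). Blood lists moved with them: of 16 myeloid, 13 erythroid, 5 platelet and 10 interferon response genes 1, 2, 2 and 1 fell, with relative medians of -59.2, -60.5, -53.0 and -55.7 (1.64e-09, 4.1e-08, 0.00111 and 0.000163; 0.00939, 0.0251, 0.036 and 0.0466 with an estimated correlation). limma called 259 genes between newborn and microfractured adult bulk tissue, 77 higher and 182 lower, of which 251 differed by at least 50 points, and groups did not overlap for 19.8% (chance 10%). A logit of the score called 101 higher and 109 lower. The split was 32 higher and 244 lower without newborn replicate 1, 90 and 268 without replicate 2 and 31 and 172 without replicate 3. With a filter at the 75th percentile it was 18 and 126. The count was 95 without microfractured replicate 1, 133 without replicate 2 and 78 without replicate 3. It was 0 with a block for the replicate number and 0 with the 2 groups fitted alone, 144 with a filter at the 75th percentile, 405 with a mean over probe sets and 439 without a variance trend.

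**Figure D3:**
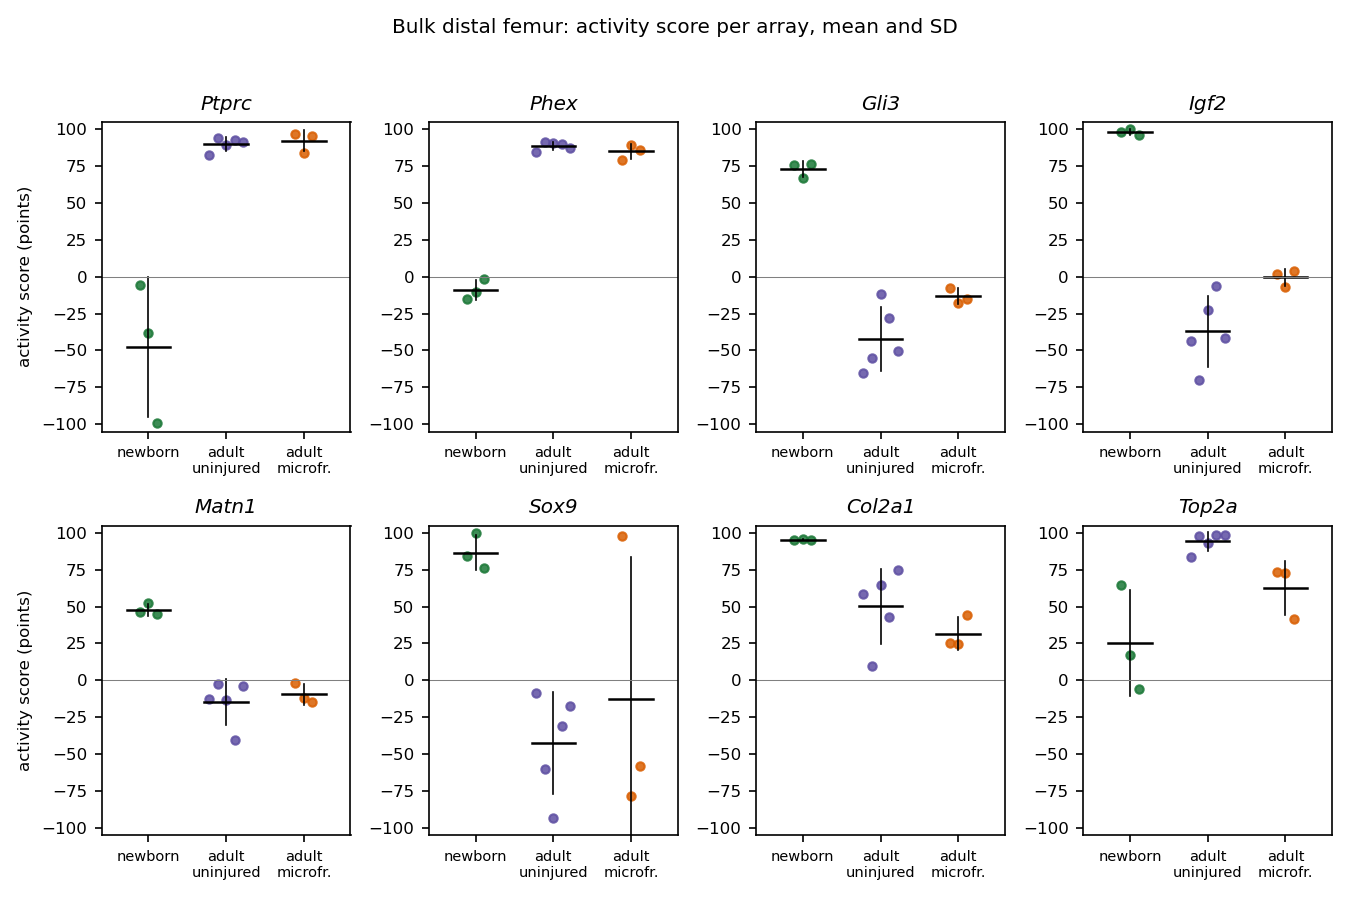
Activity scores of named genes in bulk tissue on a scale from -100 to 100, with points for single arrays, horizontal lines for means and vertical lines for the SD in newborn (3), uninjured adult (5) and microfractured adult (3) groups. Igf2 averaged 98.2, -36.9 and -0.470 in these groups.

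**Figure D4:**
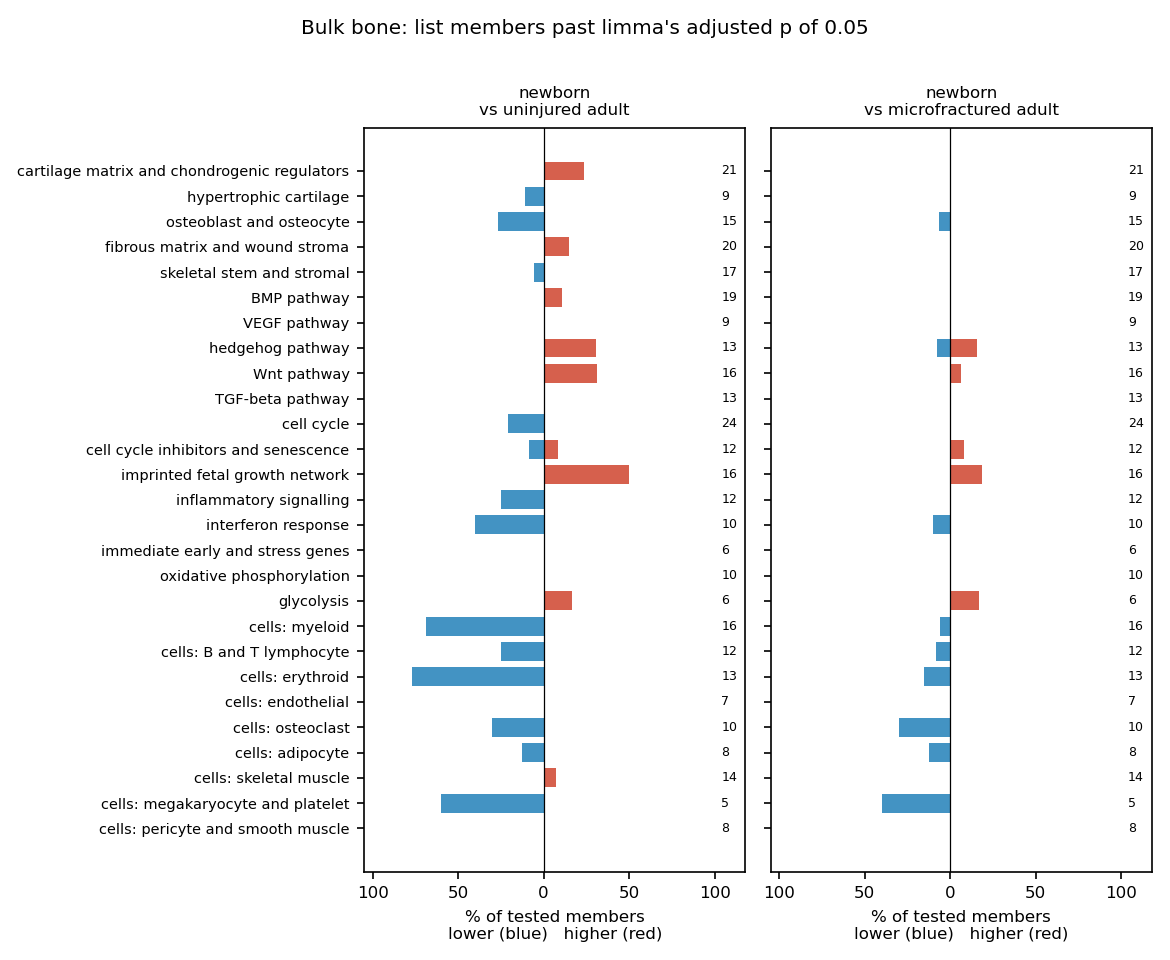
Bars give the percentage of each list's tested genes called higher (right) or lower (left) by limma when newborn bulk tissue is set against uninjured or microfractured adult tissue, with the number tested at the right. Of 16 myeloid genes, 11 were lower than in uninjured adults and 1 was lower than after microfracture.

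No single gene passed between microfractured and uninjured adult bulk tissue. Sox9 read -13.0 ± 96.4 after microfracture and -42.3 ± 34.6 without (SD, n = 3 and 5; adjusted p = 0.815), Col2a1 31.6 ± 11.1 and 50.1 ± 25.3 (0.725), Bmp2 56.0 ± 28.9 and 87.8 ± 9.48 (0.412), and Ptprc differed by 2.31 ± 19.36 points (0.982). The smallest p among higher genes was that of Tmem198b (74.5 ± 10.9 against -70.2 ± 20.7) and among lower genes that of Klhl25 (-87.1 ± 5.42 against 55.1 ± 25.9), both at adjusted p = 0.135. limma called 0 of 16587 genes, with 1645 at an unadjusted p under 0.05 where 829 were due by chance, and groups did not overlap for 9.68% (chance 3.57%). Without microfractured replicate 2 the count was 67, and it was 1 without uninjured adult replicate 1 and 1 without replicate 2. Array weights gave 9 and the 2 groups fitted alone gave 2. Camera passed no list, while fry passed fibrous matrix (0.029), hedgehog (0.0353) and imprinted growth genes (0.029), whose relative medians were 15.80, 26.71 and 11.59. Median, mean and tests differed in sign for the cartilage, VEGF, adipocyte, muscle, platelet and pericyte lists.

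The microfracture differences of sorted cells and bulk tissue were compared over 8474 genes tested in both. They correlated across genes at r = -0.103 (Spearman's rho -0.0791), and 48.4% had the same sign; genes are not independent replicates. No gene was called in both, as limma called 0 in bulk tissue. At an unadjusted p under 0.01, 20 genes were higher in both (10.4 by chance) and 12 lower in both (26.3 by chance).

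The factor arrays asked what BMP2, a bone and cartilage inducer, and VEGFR1, a receptor that binds VEGF, did to stem cells of microfractured joints. There was 1 array per treatment, so no value has a replicate check and no p was computed. Under BMP2 the score of Bmp2 was 76.83 against 36.2 with PBS, while Col2a1 (94.36 and 94.68), Runx2 (99.78 and 99.3) and Vegfa (99.75 and 99.83) sat near the upper bound with either. Sox9 scored -10.35 with PBS, -9.43 with BMP2 and 5.21 with VEGFR1, and Acan 39.15, 49.63 and 29.93. Genes chosen after their values were seen were the BMP antagonist Nog (-40.36, 62.88 and -8.64), the mineralization genes Alpl (-7.56, 66.18 and -12.97) and Dmp1 (-30.43, 50.17 and -11.72), the VEGF relative Pgf (-27.07, 55.37 and 41.4), the cartilage gene Snorc (-94.98, -3.67 and -32.65) and the hedgehog ligand Shh (75.49, -36.77 and -33.23). Only 2 of 17 osteoblast genes and 2 of 22 BMP pathway genes were at least 50 points higher with BMP2 than with PBS, and 1 BMP pathway gene was lower.

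Of 7047 genes compared, 952 differed by at least 50 points between BMP2 and PBS, 465 higher and 487 lower. Of 6974 genes, 804 differed between VEGFR1 and PBS, 419 higher and 385 lower, and of 7034 genes 958 differed between BMP2 and VEGFR1. The largest differences were Cplane2 (178.49) and Akap13 (-180.42) under BMP2 and Catsper2 (178.42) and Ap5z1 (-177.55) under VEGFR1. Osteoblast genes scored a median of 12.18 points higher with BMP2 than with VEGFR1, the 99.3 percentile of random lists, and 5.03 points higher than with PBS (94.2 percentile). Against PBS the myeloid (8.61 points, 98.8 percentile), interferon response (9.26, 97.2), immediate early (9.26, 96.9), hypertrophic cartilage (5.235, 95.1) and endothelial lists (4.68, 94.4) ranked higher with BMP2 than the osteoblast list. Ranks over single arrays were taken for many lists, so some extreme ranks arise by chance. Cartilage genes differed by -0.065 points with BMP2 (53.3 percentile) and 0.475 points with VEGFR1 (65.5 percentile) against PBS. Both factors moved 423 genes the same way, 217 higher and 206 lower (31.4 each by chance), but both used the same PBS array: the differences correlated at 0.449, and independent noise sharing an array gives 0.50. With a mean over probe sets the counts against PBS were 486 and 422, and without a filter 2378 and 2157.

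**Figure D5:**
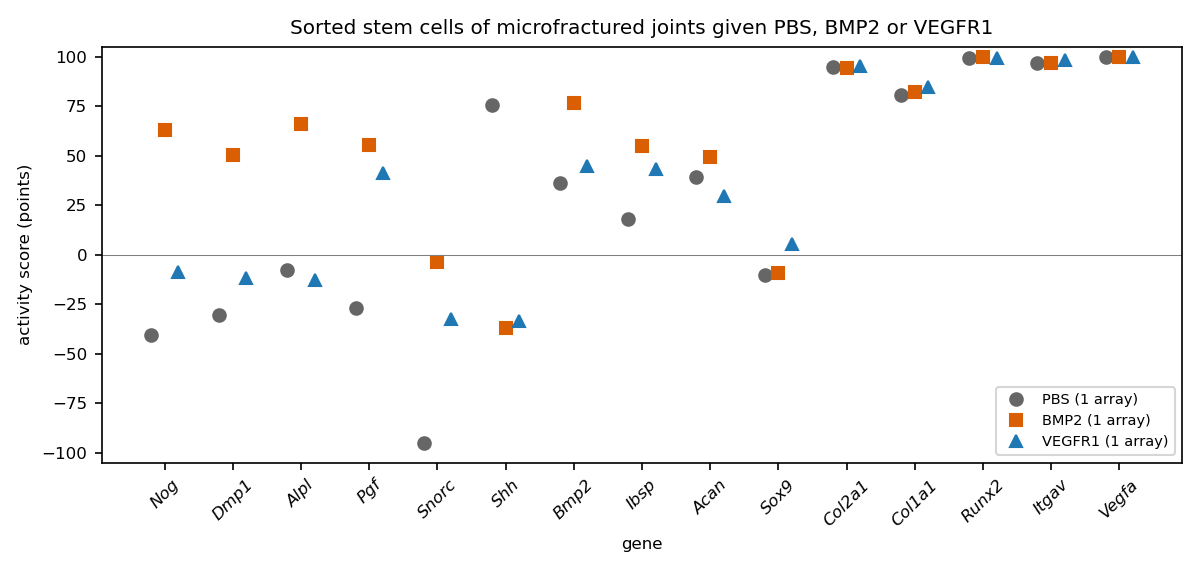
Activity scores of named genes in the 3 single arrays of stem cells from microfractured joints given PBS, BMP2 or VEGFR1, with 1 point per array. Nog scored -40.36, 62.88 and -8.64 in these arrays.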

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

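The test of a raised low end for the blood markers and the spread of the test of scale were chosen only after the result was seen. The other tests in this part had bounds written beforehand, but the patterns came from these data.

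Single arrays stood apart from their groups in 9 of 132 values tested, where chance gives about 1 in 20. The number is the gap to the nearest array over the range of the group. In newborn stem cells these were Alpl in replicate 2 (0.842), Aurkb in replicate 4 (0.896), C1qtnf3 in replicate 1 (0.943) and Sfrp4 in replicate 4 (0.916). In uninjured adult bulk tissue they were Ccna2 (0.935) and Rsad2 (0.75) in replicate 1, Runx2 in replicate 2 (0.855), and Epb42 (0.770) and Thbs2 (0.807) in replicate 5.

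For some genes the groups did not overlap in sorted cells or in bulk tissue but lay in opposite order, and the difference between sorted cells and bulk tissue was not tested. This held for 21 of 270 gene comparisons. The bulk difference passed only for Chad, Dkk3, Thbs2, Rrm2, Top2a and Ccna2 in newborns against uninjured adults. After microfracture none passed in bulk tissue (adjusted p = 0.188 to 0.838), nor did any in newborns against microfractured adults (0.109 to 0.568). In sorted cells Meg3 after microfracture and Rrm2 in newborns against uninjured adults (0.117) did not pass. After microfracture, means that were lower in sorted cells and higher in bulk tissue were those of Cd3g (10.7 points in bulk), H2-M10.1 (85.0), Meg3 (38.2) and Zdbf2 (75.3). In newborns against uninjured adults they were those of Col2a1 (45.3), Igfbp1 (10.097), Prg4 (36.6), Chad (95.3), Dkk3 (84.6) and Thbs2 (79.0). The division genes Rrm2 (-58.2), Cdk1 (-18.2), Aurkb (-29.1), Top2a (-69.0) and Ccna2 (-42.8) had means the other way. In newborns against microfractured adults, those of Col2a1 (63.8), Col1a1 (25.85), Chad (87.4), Cdon (63.0) and Thbs2 (26.3) were lower in sorted cells and higher in bulk tissue, and Rrm2 (-40.7) the reverse.

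Blood cell markers were higher in uninjured adult stem cells than in the other sorted groups. Genes rich in marrow, taken as those lower in newborn than adult bulk tissue, moved -0.91 relative to other genes after microfracture. This is consistent with RNA of marrow cells in those arrays, although the gate removes CD45, TER119 and TIE2 cells, and 21 of 31 blood markers tested are themselves among these genes. Of the lowered blood markers, 75% lay above the 99th percentile of olfactory and vomeronasal receptor genes in those arrays (653 intensity units). But these markers had passed the filter and fallen from those same arrays, which favours high values there. The share therefore does not settle whether a raised low end of the signal was the whole cause. A change in the cells themselves was not tested and stays open.

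Single genes of other tissues, such as H2-M10.1, Prl3d1 and Igfbp1, were among the largest falls after microfracture, and no list of such genes was tested. Olfactory and vomeronasal receptor genes, a different set measured without a filter, differed by a median of -1.69. A raised low end of the signal in uninjured adult arrays may therefore account for such falls. The scale between arrays stays open as well: 56.8% of strongly lowered genes outside the marrow group were still called lower after quantile normalization, but this share was 48.7% to 73.8% with single arrays left out and 52.6% after median-centring, which straddles the bound of 50% set for it. No biological explanation was tested.

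Xist, the RNA of the inactive X chromosome, was higher in newborn than adult stem cells (6517 against 258 uninjured and 44.0 microfractured). Single arrays did not overlap (5943 to 7008, 134 to 325 and 15.1 to 70.9 in the same order). Unequal sex of the animals may contribute: the mean of 4 Y-linked genes was lower in newborns by a log2 difference of -0.71 at the least, and by -43.8 points in bulk tissue. The newborn bulk arrays disagreed among themselves (mean of these genes 36.6 ± 49.0, SD, n = 3, from 7.295 to 93.1), and Xist differed by 47.3 points there, short of the 50 points set beforehand. The bounds set beforehand were met in neither kind of sample, so these values do not settle it. The Y-linked gene Eif2s3y was still read in newborn stem cells (595 against 1198 uninjured and 1654 microfractured). That does not argue against unequal sex, since the labels do not say that an array held 1 sex only. The labels give no sex, so sex and age cannot be told apart for these genes. Unequal sex may also reach other genes in the comparisons of newborns with adults.

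Other splits of the arrays were tried for each count. They treat arrays as separate units, and the labels do not say that these are separate animals, so differences between a few animals were not tested. Only 1 of 35 splits, the real one, reached the count for newborn against uninjured adult stem cells (5945 genes, at most 1 in other splits). The same held for newborn against microfractured adult stem cells (3997, at most 0, 1 of 35) and newborn against uninjured adult bulk tissue (1087, at most 31, 1 of 56). These shares met the bound set beforehand against a chance division, but they are the smallest that the splits can give. Other splits mix groups that differ, which widens the spread and lowers their counts, so chance is not excluded. For microfractured against uninjured adult bulk tissue (0, at most 27) any split reaches a count of 0, so 56 of 56 did by construction and the splits decide nothing there. For microfractured against uninjured adult stem cells (3606, at most 0) and newborn against microfractured adult bulk tissue (259, at most 2), 10 splits are too few.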

How the results depend on the processing

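The runs without marrow-rich genes, without X and Y genes, with a logit and without both bulk arrays that stood apart were chosen after the result was seen. The cause of changed counts was not tested.

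For microfractured against uninjured adult stem cells (3606 genes), centring gave 5811, no filter 6242, a filter at the 75th percentile 1742 and the 2 groups alone 2262. Leaving out single arrays gave 1806 (uninjured adult replicate 1, with 9824 genes tested) to 4150. Without marrow-rich genes 3308 were called, but only 493 of 10893 tested genes were removed, so the count had little room to change. Without X and Y genes 3510 were called. For newborn against uninjured adult (5945), no filter gave 9549 and the 75th percentile 3369, with 4300 to 5519 leave-one-out. For newborn against microfractured adult (3997) the 75th percentile gave 2628, with 3248 to 4018 leave-one-out.

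In bulk tissue, newborn against uninjured adult (1087) gave 719 at the 75th percentile and 0 with a replicate block, and 609 (without uninjured adult replicate 3) to 1064 leave-one-out. Newborn against microfractured adult (259) gave 144 at the 75th percentile, 439 without trend, 405 with a mean of probe sets, 0 with a replicate block, 0 with the 2 groups alone, and 78 (without microfractured replicate 3) to 358 leave-one-out. Microfractured against uninjured adult gave 0 (limma; 1645 at an unadjusted p under 0.05), 9 with array weights, 2 with the 2 groups alone, and 0 to 67 (without microfractured replicate 2) leave-one-out. Without both arrays that stood apart the counts were 761, 180 and 0.

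Same-numbered arrays did not pair: their deviations correlated at -0.0430 to 0.278 in sorted cells and -0.221 to 0.111 in bulk. With a replicate block the sorted counts were 3276, 5241 and 3466. In bulk tissue only uninjured adults had replicates 4 and 5. The block there spent those arrays on their own terms and left less information on the spread. The loss of bulk calls with a block may follow from this design.

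Lists past 0.05 fell with an estimated correlation from 7 to 0, 13 to 1 and 13 to 1 in the sorted comparisons, and from 16 to 8 in both newborn bulk comparisons. With fry they were 14, 25 and 21 in sorted cells and 3 in bulk after microfracture. Factor counts were 2378 (BMP2) and 2157 (VEGFR1) without a filter and 486 and 422 with a mean of probe sets. The sorted correlation of 0.592 was 0.653 with quantile normalization and 0.676 without a filter, and 0.540 to 0.610 leave-one-out. The bulk one was 0.311 to 0.492. Overlap between sorted cells and bulk was 32 at an unadjusted p under 0.01.

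Of 181 gene results 109 held in every setting in which the gene was tested. Of 3303 values 3013 were the same, 271 weaker, 19 stronger and 0 reversed. A gene dropped in a setting gave no value there and could still count as held. After microfracture in sorted cells, 30 of 38 genes were tested at the 75th percentile and 32 without marrow-rich genes. Some were also missing when single arrays were left out, so those runs did not check them. The parts differed: in sorted cells 39 of 39 results held for newborn against uninjured adult, 31 of 33 for newborn against microfractured adult and 28 of 38 after microfracture. In bulk tissue 2 of 42, 0 of 18 and 9 of 11 held in the same order, and a replicate block weakened 37 of the 42 and 16 of the 18. The 11 bulk results after microfracture did not pass to begin with, so their holding shows little, although it counts towards the 109. A mean over probe sets for sorted cells (1 row per gene), pseudocounts for scores, the identical second tables and a test of sorted cells against bulk were not run.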

Other observations

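Both patterns in this part were noticed after the results were seen.

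The cell cycle list moved in opposite directions in the 2 kinds of newborn sample. Of its genes, 13 of 21 were higher in newborn than in uninjured adult stem cells, and 5 of 24 were lower in newborn bulk tissue. Both list calls ended with an estimated correlation (adjusted p = 0.185 in sorted cells and 0.0764 in bulk tissue), and the difference between the kinds was not tested.

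In newborn against uninjured adult bulk tissue the myeloid and erythroid lists had the lowest relative medians (-75.08 and -83.81). The cause was not tested.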
